A study of Homo sapiens with 12 samples.

How the data were processed

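RNA from 12 samples of HEK293T cells, 2 independently transfected replicates in each of 6 groups, harvested 48 h after transfection, was measured on Illumina bead arrays. Per the labels, biotinylated cRNA was made from total RNA with a kit that primes from poly(A). The deposited scanner table holds for each array an intensity per probe, the average bead signal on a linear scale with no negative values and array medians that differ, so it was taken as not normalized between arrays. The deposited table also gives a detection p-value per probe and array, in steps that imply 770 negative control beads. The authors also deposited an intensity table with values below 0 and equal quantiles over the 12 arrays, which was taken from its values as background-subtracted and quantile-normalized. The authors used GenomeStudio 2011.1, and the background and averaging options are not given in the sources used here.

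The scanner intensities were background-corrected with the nec function of limma 3.58.1 in R 4.3.3, with the negative control distribution inferred from the detection p-values. An offset of 16 was added, the arrays were quantile-normalized on the linear scale, and the log2 was then taken. Probes with a detection p under 0.01 on at least 2 of the 12 arrays were kept, 17814 of 47323. Of all probes 30113 carried 1 gene symbol, 8 several and 17202 none, and 3908 detected probes without a symbol were left out of the gene comparisons. Each gene was represented by its brightest detected probe, which gave 10645 genes, of which 2663 had several detected probes. Of the probes with 1 symbol 30074 matched a RefSeq gene table, and probe positions within messages were not analysed here.

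A linear model with 1 mean per group was fitted to all 12 arrays with limma, and 12 comparisons were tested with moderated statistics and Benjamini-Hochberg adjustment within each comparison at an adjusted p of 0.05. Replicate SDs and fold bounds come from the normalized values. Where a probe was not detected on 1 or both arrays of 1 group, the fold is a lower bound with those arrays at their detection floor, and no fold is given where this holds for both groups. In comparisons of 4 groups no size is given where a named gene was not detected in some of them. The labels do not say whether replicate numbers pair transfections across groups. The replicate differences of 15 pairs of groups correlated at 0.246 to 0.477, all above the preset minimum of 0.1, so values with the replicate number as a block stand beside the results. Replicates of a group correlated at 0.980 to 0.987 across genes. With only 2 replicates, a control group cannot be split to give a comparison without effect.

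The groups, comparisons, gene lists, rule for named genes and alternative settings were set before the data were examined. GADD45A, ING1 and MAGEB2 were always named. For each comparison the rule took, among passing genes whose 2 groups' arrays did not overlap, the 12 largest rises, the 12 largest falls and up to 4 passing members of each list. Where fewer than 5 genes passed in a direction, all were taken with the 3 of smallest p given as values that did not pass. The 23 lists were apoptosis regulators, blood cell markers, cholesterol biosynthesis, the DNA methylation and demethylation machinery, epithelial markers, fibroblast and mesenchymal markers, G1/S and DNA replication genes, G2/M genes, GADD45 family and stress kinase response genes, germline and cancer-testis genes silenced by DNA methylation, heat shock and chaperones, histone acetyltransferase and H3K4 methyltransferase genes, histone genes, hypoxia and glycolysis, ING proteins and the SIN3-HDAC complex, interferon-stimulated genes, neuronal markers, NF-kB targets, nucleotide excision repair, oxidative phosphorylation, p53 targets, ribosomal proteins, and the unfolded protein and ATF4 response. They were written from general knowledge and tested with camera (preset correlation 0.01, and estimated) and fry, adjusted over the 23 lists within a comparison. Members were also adjusted over the list alone.

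The alternatives were no background correction, an offset of 50, median or 75th percentile scaling, the authors' deposited values, no detection filter, detection on all 12 arrays, probes tested singly, the mean over a gene's probes, eBayes with trend and robust, array weights, the replicate block, only the groups compared, an adjusted p under 0.01, at least 1.5-fold, and leaving out each array in turn. In the last, the lone array of a group is assumed to vary like the other groups. The procedure was tested on simulated data, in which 200 of 10645 genes were changed in ING1b against control. It recovered 3 of 67 genes at 1.5-fold, 36 of 67 at 2-fold and 65 of 66 at 4-fold with 2 false calls, and with the replicate block 22, 61 and 66 with 13 false calls. The simulated replicate shift was the same in all groups and the noise came from the blocked fit. The higher recovery with the block was thus built in and does not show that replicate numbers pair. A shift of 0.5 in 1 of 23 lists of 20 genes was called by camera with either correlation and by fry, with 0 false calls. In this single run list members were drawn at random with independent noise. It therefore does not test camera on lists whose genes vary together. Comparisons with shared controls and no effect were simulated 100 times. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.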

Results

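Gene expression was measured in HEK293T cells, a human embryonic kidney cell line, 48 h after transient transfection. The 6 groups received an empty vector, human GADD45a, human ING1b, both proteins, ING1b without its PHD domain (ING1bΔPHD), or GADD45a with ING1bΔPHD. GADD45a is a stress-induced protein linked to DNA demethylation, and ING1b is a tumour suppressor whose PHD finger binds trimethylated lysine on histone H3. Each group had 2 independently transfected replicates, so 12 bead arrays were compared. Between 14555 and 16301 of the 47323 probes were detected per array, and the median signal per array ran from 129 to 140 intensity units. The number of arrays limits the precision of every value. Changes are log2 differences between group means, each with the standard error (SE) of the limma fit over 12 arrays and n = 2 per group. A gene rose or fell where its limma adjusted p was under 0.05.

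The 2 transfected genes were read first. One of the 2 GADD45A probes, ILMN_1694075, went against the labels. Its signal before any correction was 744 to 1088 on the 6 arrays without GADD45a in their label and 128 to 160 on the 6 arrays with it, where it was not detected. It was at least 11.8-fold lower in the arrays labelled GADD45a than in the control arrays (limma adjusted p = 0.000363), at least 11.2-fold lower in those labelled GADD45a+ING1b (0.000269) and at least 10.8-fold lower in those labelled GADD45a+ING1bΔPHD (0.000594). The second GADD45A probe, ILMN_2052208, differed from the control by -0.53, -0.16 and -0.49 in the same groups and did not pass. Of the 4 ING1 probes 1 was detected, and it differed from the control by 0.30 in ING1b, 0.22 in GADD45a+ING1b, 0.23 in ING1bΔPHD and 0.49 in GADD45a+ING1bΔPHD (SE 0.181), none of which passed. Both probes of MAGEB2, a cancer-testis gene studied earlier as a target of GADD45a-dependent demethylation, were detected on 0 arrays. Their group means ran between 4.55 and 5.31 on the log2 scale in all 6 groups. Since the first probe went against the labels, groups are named below by their labels. These values do not exclude that arrays with and without GADD45a were exchanged as a whole. In that case GADD45a against control would be turned around, and so would GADD45a+ING1b against ING1b and both tests of interaction. ING1b against control would be GADD45a+ING1b against GADD45a, and the reverse. GADD45a+ING1b against control would be ING1b against GADD45a. The groups with ING1bΔPHD would change in the same way. Comparisons of the PHD domain with and without GADD45a would change places, and the test between them would be turned around.

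In the arrays labelled GADD45a against the control arrays, 20 genes rose and 50 fell. The largest rise was at 1 of the 3 probes of GGTLC1, a gamma-glutamyltransferase light chain gene with close paralogs, whose probe ILMN_1680730 was at least 15.0-fold higher (limma adjusted p = 0.000496). Its other detected probe changed by 0.02. TNFRSF12A, the receptor for the cytokine TWEAK, rose 3.51-fold (log2 1.81, SE 0.206, adjusted p = 0.00574), TFPI, an inhibitor of coagulation, rose 2.41-fold (log2 1.27, SE 0.147), and the transcription factor ETV5 was at least 1.17-fold higher. Among genes that fell were the Mediator subunit MED29 (-2.25, SE 0.202), the complex I subunit NDUFA13 (-2.15, SE 0.215), the serine synthesis enzyme PSAT1 (-1.95, SE 0.247) and the smooth muscle actin ACTA2 (-1.61, SE 0.198). INF2, an actin-binding formin, fell at 1 of its 3 detected probes (-2.04, SE 0.152), and the other two changed by 0.09 and 0.15.

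Of 21 measured p53 targets, 2 fell in the arrays labelled GADD45a: XPC, which recognises DNA damage in nucleotide excision repair (-0.97, SE 0.161), and the sestrin SESN1 (-0.77, SE 0.142). Adjusted over the list alone, 6 fell. The list's median was -0.28 (camera adjusted p = 0.00764; adjusted p = 0.62 with an estimated correlation; 0.109 without GADD45a replicate 2). Of 17 heat shock and chaperone genes, 0 passed limma over all genes and 1 adjusted over the list alone, and the median was 0.43 (camera adjusted p = 0.000183; adjusted p = 0.62 with an estimated correlation; 0.0667 without Control replicate 2). Single members of other lists passed: JUN, a stress-responsive AP-1 subunit, rose (0.94, SE 0.175), SC5D of cholesterol synthesis rose (0.76, SE 0.135) and the spindle factor TPX2 fell (-1.18, SE 0.196). With the replicate number as a block, 391 genes passed (146 up, 245 down). Under median scaling 434 passed (26 up, 408 down), where the median of all genes moved by -0.23. The count was 144 without Control replicate 1, 6 without Control replicate 2, 5 without GADD45a replicate 1, 9 without GADD45a replicate 2, 37 without either ING1b array and 46 without either GADD45a+ING1bΔPHD array. Of 30 named genes, 0 were tested and passed in all 27 alternatives, and GGTLC1 passed in the 26 in which it was tested.

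Full-length ING1b against the control raised 40 genes and lowered 6. DHRS2, a short-chain dehydrogenase, was at least 16.5-fold higher (limma adjusted p = 3.06e-05), and its second detected probe was at least 8.17-fold higher. TCEAL7 was at least 4.68-fold higher at 1 of its 2 probes. GADD45B, a stress-induced paralog of GADD45A, rose 4.32-fold (log2 2.11, SE 0.167, adjusted p = 0.000841), and TUBB3, a tubulin typical of neurons, rose 2.82-fold (log2 1.49, SE 0.147, adjusted p = 0.00164). RNA5S9, a 5S ribosomal RNA gene, rose 29.7-fold (log2 4.89, SE 0.711), and by 5.85 without Control replicate 1 and 3.94 without Control replicate 2. The RNA5S9 call was lost in the latter case (adjusted p = 0.16) and without ING1b replicate 1 (0.184) or ING1b replicate 2 (0.12). RNA5S9 means were 8.86 in control, 8.78 in GADD45a, 13.75 in ING1b, 14.09 in GADD45a+ING1b, 12.35 in ING1bΔPHD and 11.94 in GADD45a+ING1bΔPHD, and 5S RNA lacks a poly(A) tail, from which the labelling was primed. NOP53, a ribosome assembly factor, fell (-1.68, SE 0.206), as did TBL1X (-1.45, SE 0.207) and the ribosomal protein gene RPS9 (-0.83, SE 0.138).

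Histone genes were the gene group with the smallest p in ING1b. Of 15 measured, 5 rose (H2BC5, H2BC11, H2AC18, H2BC21 and H4C8), and 10 rose adjusted over the list alone, with a list median of 0.85 (camera adjusted p = 2.16e-13; adjusted p = 0.0293 with an estimated correlation). H4C8 was at least 2.88-fold higher, H2BC5 rose by 1.56 (SE 0.153), H2BC21 by 1.45 (SE 0.192) and H2AC18 by 1.30 (SE 0.15). As background, replication-dependent histone messages mostly lack a poly(A) tail and the labelling was primed from poly(A), and members of these families are similar enough to share probes. Of 19 GADD45 family and stress kinase response genes, 3 rose: GADD45B, and the immediate-early transcription factors EGR1 (1.95, SE 0.247) and FOSB (at least 3.23-fold). Adjusted over the list alone 8 rose (camera adjusted p = 1.32e-05; adjusted p = 0.0293 with an estimated correlation). The chaperone genes HSPA6 (at least 3.84-fold), which has close paralogs and a second probe detected in neither group, and DNAJB1 (1.27, SE 0.208) rose among 17 in their list.

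The other calls in ING1b did not hold with an estimated correlation. They were heat shock (median 0.19, camera adjusted p = 0.00354; adjusted p = 0.428 with an estimated correlation), interferon-stimulated genes (median 0.27, 0.00342; adjusted p = 0.332 with an estimated correlation), blood cell markers (median 0.60 over 4 genes, 0.023; adjusted p = 0.26 with an estimated correlation), cholesterol synthesis (median 0.22, 0.023; adjusted p = 0.357 with an estimated correlation) and the unfolded protein and ATF4 response (median -0.41, 0.00163; adjusted p = 0.405 with an estimated correlation). Of these, all but the interferon list had an adjusted p between 0.246 and 0.894 without Control replicate 2, and the interferon list had 0.121 without Control replicate 1. Without ING1b replicate 2, heat shock and blood cell markers had 0.0598 and cholesterol synthesis had 0.374. With the replicate number as a block, 85 genes passed (66 up, 19 down). The count was 13 without Control replicate 2, 8 without ING1b replicate 1 and 18 without ING1b replicate 2. Of 31 named genes, GADD45B, H2BC5, LGALS1 and TUBB3 passed in all 27 alternatives. CCDC22, DHRS2 and TCEAL7 passed in the 26, and MYBPHL and SPANXA2 in the 24, in which their probes met the detection filter and were tested.

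The arrays labelled GADD45a+ING1b differed from the control at 286 genes, with 168 up and 118 down. DHRS2 was at least 20.6-fold higher (limma adjusted p = 1.63e-05), and the GGTLC1 probe at least 15.2-fold higher (0.000139). VGF, a neuropeptide precursor, rose 10.7-fold (log2 3.42, SE 0.232), EGR1 rose 9.68-fold (log2 3.27, SE 0.247), FOSB at least 7.00-fold, GADD45B 7.07-fold (log2 2.82, SE 0.167) and TUBB3 5.89-fold (log2 2.56, SE 0.147). NDUFA13 (-2.11, SE 0.215), PSAT1 (-1.95, SE 0.247), NOP53 (-1.85, SE 0.206), SAC3D1 (-1.83, SE 0.148) and MED29 (-1.80, SE 0.202) fell. VCX3B, a testis gene with near-identical paralogs, was at least 2.73-fold higher, and RNA5S9 rose 37.5-fold (log2 5.23, SE 0.711), and by 6.18 without Control replicate 1 and 4.28 without Control replicate 2. The RNA5S9 call was lost in the latter case (adjusted p = 0.0508) and without GADD45a+ING1b replicate 1 (0.0604).

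Of 19 GADD45 family and stress kinase response genes, 3 rose in GADD45a+ING1b (GADD45B, FOSB and EGR1) and 11 adjusted over the list alone, with a median of 0.67 (camera adjusted p = 2.49e-06; adjusted p = 0.0308 with an estimated correlation). Of 15 histone genes, 7 rose, and 12 rose and 1 fell adjusted over the list alone (median 0.86, camera adjusted p = 1.19e-08; adjusted p = 0.0841 with an estimated correlation). Of 17 heat shock genes, HSPA6 (at least 7.11-fold, and at least 1.59-fold at its second probe) and DNAJB1 (2.33, SE 0.208) rose, and 4 adjusted over the list alone (median 0.37, camera adjusted p = 7.16e-05; adjusted p = 0.366 with an estimated correlation). Among 21 p53 targets, SPATA18 (-1.12, SE 0.214), XPC (-1.04, SE 0.161) and PHLDA3 (-0.92, SE 0.184) fell, and 5 fell and 1 rose adjusted over the list alone (median -0.32, camera adjusted p = 0.0178; adjusted p = 0.366 with an estimated correlation). That list had an adjusted p of 0.102 under median scaling, 0.0676 without Control replicate 1 and 0.0759 without GADD45a+ING1b replicate 2. BRMS1 (1.10, SE 0.246) and SAP130 (0.75, SE 0.168), subunits of SIN3-HDAC complexes, rose among 20 ING and SIN3-HDAC genes, and ISG20 (1.27, SE 0.187) and IRF7 (at least 1.31-fold) rose among 14 interferon-stimulated genes.

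Smaller list shifts in GADD45a+ING1b were called by camera and not with an estimated correlation. Blood cell markers, with CD14 rising (at least 2.53-fold) among 4 measured, had a camera adjusted p of 0.0104 (adjusted p = 0.149 with an estimated correlation; 0.0628 without GADD45a+ING1b replicate 2). Neuronal markers, with TUBB3 and CHGA rising among 10, had 0.028 (adjusted p = 0.366 with an estimated correlation; 0.334 without Control replicate 2; 0.0759 without GADD45a+ING1b replicate 2). Cholesterol synthesis, with MVD (1.09, SE 0.248) and SC5D (0.72, SE 0.135) rising among 16, had 0.0178 (adjusted p = 0.366 with an estimated correlation; 0.313 without Control replicate 2; 0.0759 without GADD45a+ING1b replicate 2). The unfolded protein and ATF4 response, with PSAT1 falling among 23, had 0.0166 (adjusted p = 0.529 with an estimated correlation; 0.64 without Control replicate 2; 0.0659 without GADD45a+ING1b replicate 1; 0.167 under median scaling). With the replicate number as a block, 986 genes passed (506 up, 480 down), and under median scaling 1517 passed (126 up, 1391 down), where the median of all genes moved by -0.30. The count was 67 without Control replicate 2, 51 without GADD45a+ING1b replicate 1 and 62 without GADD45a+ING1b replicate 2, and 11 of 50 named genes passed in all 27 alternatives. Counting genes tested in only 24 to 26 of them, 25 passed wherever they were tested.

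ING1bΔPHD against the control gave 0 genes by limma, with 1179 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.228. ING1b against control had 1069 genes at an unadjusted p under 0.05. The 0 therefore does not show that ING1bΔPHD was without effect. The genes with the smallest p were TRMT44 (at least 2.07-fold, while its other detected probe was at least 1.17-fold lower) and SNORD89 (1.14, SE 0.172) upward, and ARMCX2 and RENBP (at least 2.02-fold) downward. ARMCX2 was not detected in ING1bΔPHD and its bound was 1.00-fold, which sets no size. With the replicate number as a block 3 genes passed (1 up, 2 down), among them SNORD89 and RENBP (block adjusted p = 0.039 for both), and 24 passed without Control replicate 1. Hypoxia and glycolysis genes had a median of 0.22 over 21 genes (camera adjusted p = 0.0174; adjusted p = 0.781 with an estimated correlation; 0.105 without Control replicate 1; 0.938 without ING1bΔPHD replicate 2). The unfolded protein and ATF4 response had a median of -0.27 over 23 genes (0.0174; adjusted p = 0.781 with an estimated correlation; 0.994 with the opposite direction without Control replicate 2; 0.113 without ING1bΔPHD replicate 1). Cholesterol synthesis (median 0.22) and heat shock (median 0.24) each had a camera adjusted p of 0.0427 (adjusted p = 0.781 and adjusted p = 0.786 with an estimated correlation), and 0.0594 with the replicate block. Under median scaling they had 0.0543 and 0.0527. Without Control replicate 2 they had 0.575 and 0.965, the latter in the opposite direction, and without ING1bΔPHD replicate 1 they had 0.115 and 0.122. Cholesterol synthesis had 0.114 without ING1bΔPHD replicate 2, and both lists had 0.0547 to 0.0663 without either GADD45a array, GADD45a+ING1b replicate 2 or either GADD45a+ING1bΔPHD array. In these lists 0 members passed limma, over all genes or adjusted over the list alone.

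In the arrays labelled GADD45a+ING1bΔPHD, 24 genes rose and 31 fell against the control. The GGTLC1 probe was at least 4.35-fold higher (limma adjusted p = 0.00892), a bound that was 7.34-fold without GADD45a+ING1bΔPHD replicate 1 and 2.57-fold without GADD45a+ING1bΔPHD replicate 2, and its call was lost without Control replicate 2 (0.0922). TNFRSF12A rose 3.25-fold (log2 1.70, SE 0.206), the sialidase NEU1 2.72-fold (log2 1.44, SE 0.202), and MBD1, a methyl-CpG binding protein, 2.34-fold (log2 1.23, SE 0.189; at least 1.56-fold at its other detected probe, which did not pass). MED29 (-1.81, SE 0.202), NDUFA13 (-1.72, SE 0.215), PSAT1 (-1.59, SE 0.247), ACTA2 (-1.50, SE 0.198), INF2 (-1.41, SE 0.152, at 1 of 3 detected probes) and TPX2 (-1.23, SE 0.196) fell. Among 21 p53 targets XPC fell (-1.02, SE 0.161), and 7 fell adjusted over the list alone (median -0.29, camera adjusted p = 0.018; adjusted p = 0.412 with an estimated correlation; 0.0516 with the replicate block; 0.0554 without Control replicate 1). Of 17 heat shock genes 0 passed limma over all genes and 2 rose adjusted over the list alone (median 0.28, camera adjusted p = 0.00162; adjusted p = 0.472 with an estimated correlation; 0.164 without Control replicate 2). With the replicate number as a block 645 genes passed (275 up, 370 down), and under median scaling 392 passed (33 up, 359 down), where the median of all genes moved by -0.20. The count was 226 without Control replicate 1, 0 without Control replicate 2, 4 without GADD45a+ING1bΔPHD replicate 1, 2 without GADD45a+ING1bΔPHD replicate 2, and 16 to 20 without any other array, and 0 of 26 named genes passed in every alternative in which they were tested.

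**Figure D1:**
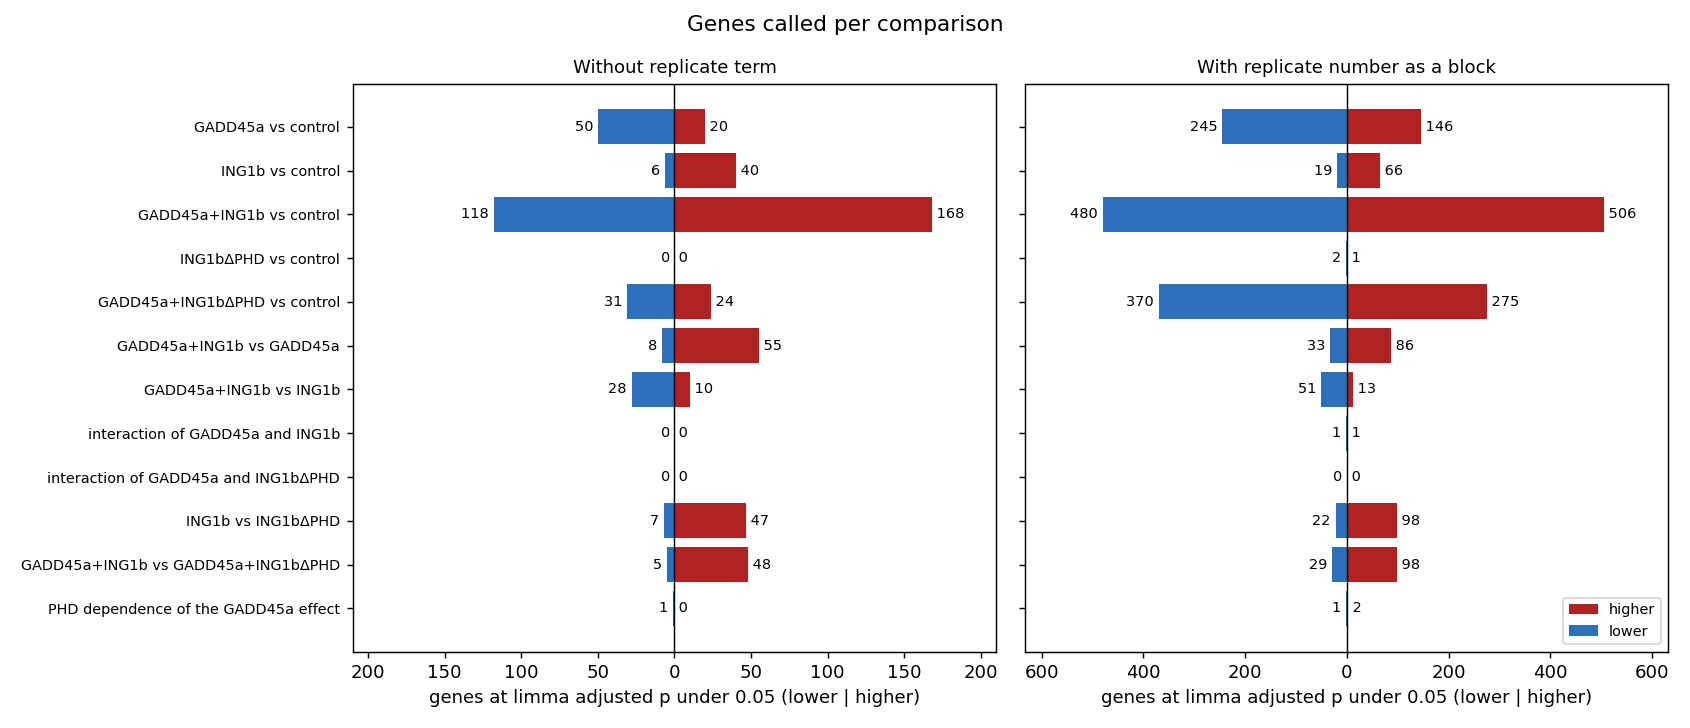
Genes that passed limma (adjusted p under 0.05) per comparison, with higher genes to the right and lower genes to the left of 0, without a replicate term (left) and with the replicate number as a block (right). ING1bΔPHD against control had 0 genes on the left and 3 on the right, and GADD45a+ING1b against control had 286 and 986.

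The 5 comparisons against control share the 2 control arrays, which by themselves make their changes correlate. Across 10645 genes, which are not independent replicates, r between pairs of these comparisons ran from 0.463 to 0.774, and 100 simulations with shared controls and no effect gave a mean r of 0.498 to 0.501. The covariance ran from 0.0515 to 0.102, against 0.0167 to 0.0168 simulated. The simulated noise came from the blocked fit and was alike in all groups. Control arrays that vary more than the others would also raise the covariance, so its excess does not measure shared effects alone. The arrays labelled GADD45a and those labelled GADD45a+ING1bΔPHD had 7 genes up and 19 down in common, where 0.0451 and 0.146 would be shared by independent calls and 0 were shared in the simulations. Since the simulations held no effect, that 0 does not measure what the shared controls add to overlaps of called genes. Part of the excess may come from them, or from the variance per gene, which all comparisons share. ING1b and GADD45a+ING1b had 29 up and 5 down in common (independent 0.631 and 0.0665), GADD45a and GADD45a+ING1b 9 up and 33 down (0.316 and 0.554), and GADD45a+ING1b and GADD45a+ING1bΔPHD 12 up and 22 down (0.379 and 0.344). GADD45a and ING1b had 0 in common (independent 0.0752 and 0.0282), and 0 genes passed in opposite directions in any pair.

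**Figure D2:**
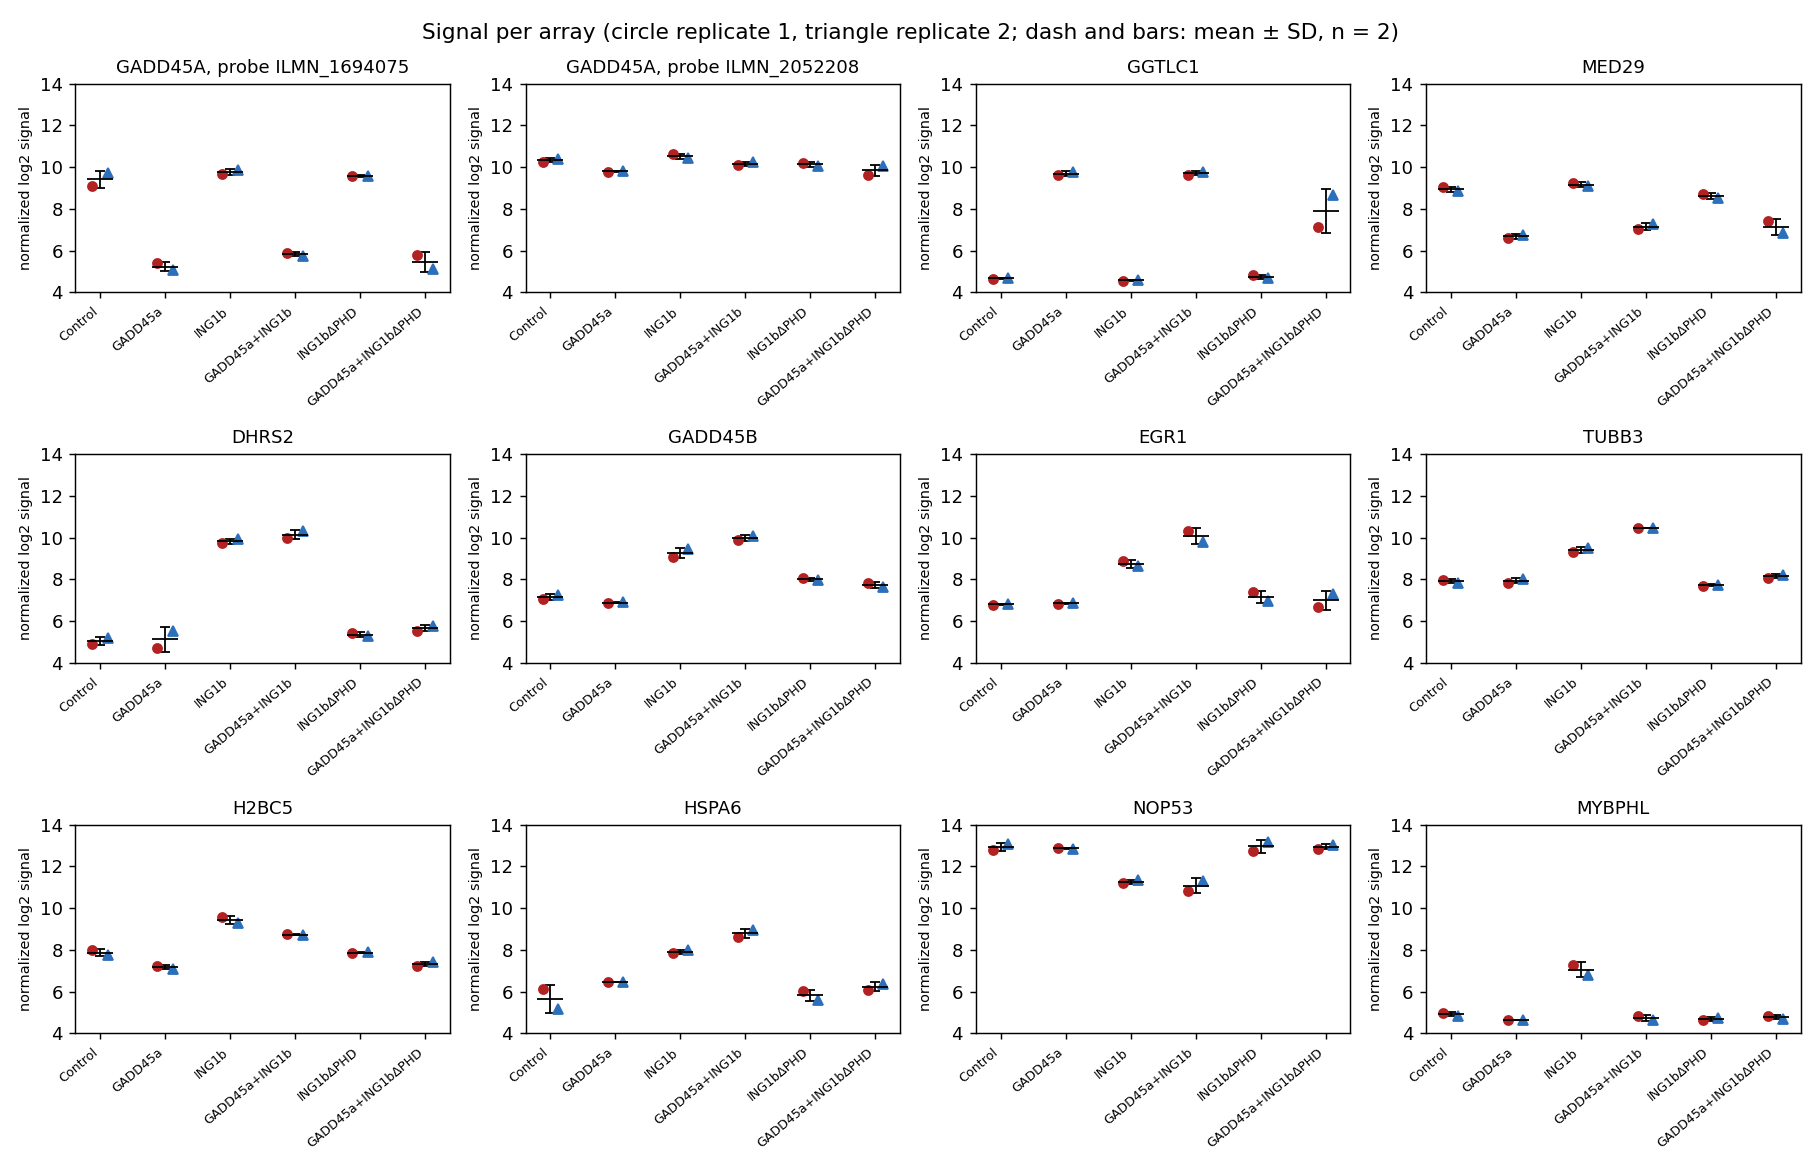
Normalised log2 signal (vertical axis) of both GADD45A probes and 10 other genes on each array, by group (horizontal axis). Circles are replicate 1, triangles replicate 2, and the dash with bars is the mean ± SD (n = 2). The GADD45A probe ILMN_1694075 is low in the 3 groups with GADD45a in their label, where GGTLC1 is high, and DHRS2, TUBB3 and EGR1 are highest in GADD45a+ING1b.

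In the arrays labelled GADD45a+ING1b against those labelled GADD45a, 55 genes were higher and 8 lower. DHRS2 was at least 19.8-fold higher (limma adjusted p = 1.90e-05), GADD45B rose 8.52-fold (log2 3.09, SE 0.167, adjusted p = 2.08e-05), TUBB3 5.77-fold (log2 2.53, SE 0.147) and EGR1 9.36-fold (log2 3.23, SE 0.247), while NOP53 fell (-1.79, SE 0.206). Of 19 GADD45 family and stress kinase response genes 5 rose: GADD45B, GADD45G, FOS, FOSB and EGR1. Adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.000269; adjusted p = 0.0442 with an estimated correlation). Of 15 histone genes 4 rose, and 9 adjusted over the list alone (median 0.68, camera adjusted p = 2.40e-11; adjusted p = 0.0442 with an estimated correlation). Interferon-stimulated genes, with ISG20 rising (1.09, SE 0.187) among 14, had a camera adjusted p of 0.00449 (adjusted p = 0.369 with an estimated correlation; 0.0998 without GADD45a replicate 1; 0.247 without GADD45a+ING1b replicate 2). Blood cell markers had 0.00554 (adjusted p = 0.118 with an estimated correlation; 0.0667 without GADD45a+ING1b replicate 2), and cholesterol synthesis 0.0278 (adjusted p = 0.369 with an estimated correlation; 0.232 without GADD45a replicate 1; 0.14 without GADD45a+ING1b replicate 2). HSPA6 (2.33, SE 0.282, and 0.08 at its second detected probe) and DNAJB1 (1.74, SE 0.208) rose, while their list had a median of -0.09 and a mean of 0.22 (camera adjusted p = 0.475). With the replicate block 119 genes passed (86 up, 33 down). The count was 24 without GADD45a replicate 1, 31 without GADD45a replicate 2, 21 without GADD45a+ING1b replicate 1 and 22 without GADD45a+ING1b replicate 2.

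In the arrays labelled GADD45a+ING1b against those labelled ING1b, 10 genes were higher and 28 lower. The GGTLC1 probe was at least 14.7-fold higher (limma adjusted p = 0.000498), VGF rose 2.75-fold (log2 1.46, SE 0.232) and TUBB3 2.09-fold (log2 1.06, SE 0.147). MYBPHL, a myosin-binding protein gene, was at least 2.17-fold lower, and NDUFA13 (-2.19, SE 0.215), MED29 (-2.02, SE 0.202) and TPX2 (-1.59, SE 0.196) fell. Of 21 p53 targets GDF15, a stress-induced cytokine (at least 4.10-fold lower), and XPC (-1.13, SE 0.161) fell, the same number adjusted over the list alone (median -0.35, camera adjusted p = 0.00047; adjusted p = 0.329 with an estimated correlation; 0.0623 without ING1b replicate 1). The GADD45 family and stress kinase list (median 0.19, camera adjusted p = 0.00347; adjusted p = 0.204 with an estimated correlation) and heat shock (median 0.14, 0.00299; adjusted p = 0.443 with an estimated correlation; 0.0659 without ING1b replicate 1; 0.0688 without GADD45a+ING1b replicate 2) had 0 members past limma over all genes, and adjusted over the list alone 4 rose and 1 fell in the former and 1 rose in the latter. Interferon-stimulated genes (median -0.14, 0.0308; adjusted p = 0.443 with an estimated correlation) and fibroblast markers (median -0.17, 0.0409; adjusted p = 0.329 with an estimated correlation; 0.087 with the replicate block; 0.21 under median scaling) also had 0, with 4 and 2 lower adjusted over the list alone. Without GADD45a+ING1b replicate 1 these lists had 0.456 and 0.384, without ING1b replicate 1 both had 0.0623, and without ING1b replicate 2 they had 0.0757 and 0.161. Both had 0.0512 without Control replicate 2, and fibroblast markers had 0.0516 without Control replicate 1, 0.0625 without ING1bΔPHD replicate 1 and 0.0632 without ING1bΔPHD replicate 2. With the replicate block 64 genes passed (13 up, 51 down), and under median scaling 58 (7 up, 51 down), where the median of all genes moved by -0.24. The count was 9 without ING1b replicate 1, 8 without ING1b replicate 2 and 10 without either GADD45a+ING1b array.

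Whether both proteins together departed from the sum of their separate log2 effects was tested by an interaction. By limma 0 genes passed, with 442 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0803. These 442 are fewer than the share of 0.05 of 10645 genes that would be reached without any effect. The closest were MYBPHL and RB1-DT downward and IQCN and TCIM upward, each with an adjusted p of 0.0803. Of the 4 groups in this test MYBPHL, IQCN and TCIM were not detected in 3 and RB1-DT in 2, so the size of their differences is set by background and not given. With the replicate block 2 genes passed (1 up, 1 down), IQCN and MYBPHL, each with a block adjusted p of 0.0409. In the same test with ING1bΔPHD 485 genes had an unadjusted p under 0.05, also fewer than a share of 0.05 of all genes tested. By limma 0 genes passed, with a smallest adjusted p of 0.174 for ITGA7 (downward, not detected in 3 of the 4 groups), and 0 with the replicate block. That count was 1 without Control replicate 1 and 1 without GADD45a+ING1bΔPHD replicate 2.

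The PHD domain was examined by comparing full-length ING1b with ING1bΔPHD, first between arrays without GADD45a in their label. The only detected ING1 probe did not pass with either construct, so the amounts of both proteins are not known here or in the next comparison. A difference in amount cannot be told apart from an effect of the domain. In ING1b against ING1bΔPHD 47 genes were higher and 7 lower with the domain. DHRS2 was at least 13.8-fold higher (limma adjusted p = 5.85e-05), TCEAL7 at least 3.91-fold and MYBPHL at least 1.99-fold. LGALS1, which encodes galectin-1, rose 4.78-fold (log2 2.26, SE 0.176, adjusted p = 0.000499), TUBB3 3.20-fold (log2 1.68, SE 0.147) and GADD45B 2.41-fold (log2 1.27, SE 0.167). NOP53 (-1.71, SE 0.206) and the elongation factor subunit EEF1D (-1.19, SE 0.164, at 1 of 2 detected probes) fell. Of 15 histone genes 5 rose, and 12 adjusted over the list alone, with a median of 1.04 (camera adjusted p = 1.55e-17; adjusted p = 0.0293 with an estimated correlation). Of 14 interferon-stimulated genes IRF7 rose, and 7 adjusted over the list alone (median 0.40, camera adjusted p = 1.32e-07; adjusted p = 0.0847 with an estimated correlation). Of 19 GADD45 family and stress kinase genes GADD45B and EGR1 rose, and 6 adjusted over the list alone (camera adjusted p = 0.00205; adjusted p = 0.0847 with an estimated correlation; 0.0584 without ING1bΔPHD replicate 1). With the replicate block 120 genes passed (98 up, 22 down). The count was 6 without ING1b replicate 1, 17 without ING1b replicate 2, 15 without ING1bΔPHD replicate 1 and 14 without ING1bΔPHD replicate 2.

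Between arrays with GADD45a in their label (GADD45a+ING1b against GADD45a+ING1bΔPHD), 48 genes were higher and 5 lower with the domain. DHRS2 was at least 18-fold higher (limma adjusted p = 5.69e-05), EGR1 rose 8.46-fold (log2 3.08, SE 0.247, adjusted p = 0.000319), VGF 7.21-fold (log2 2.85, SE 0.232), TUBB3 4.95-fold (log2 2.31, SE 0.147) and GADD45B 4.74-fold (log2 2.25, SE 0.167). ARC, an immediate-early gene of neurons, was at least 2.42-fold higher, and NOP53 fell (-1.86, SE 0.206). Of 15 histone genes 6 rose, and 10 adjusted over the list alone (median 0.94, camera adjusted p = 1.87e-13; adjusted p = 0.0455 with an estimated correlation). Of 19 GADD45 family and stress kinase genes 3 rose (GADD45B, FOSB and EGR1), and 7 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.000346; adjusted p = 0.0455 with an estimated correlation). Interferon-stimulated genes and neuronal markers each had a camera adjusted p of 0.046 (adjusted p = 0.543 with an estimated correlation; 0.0735 with the replicate block), and without GADD45a+ING1b replicate 2 they had 0.886 and 0.145, and without GADD45a+ING1bΔPHD replicate 1 they had 0.499 and 0.0979. Neuronal markers had 0.098 without GADD45a+ING1bΔPHD replicate 2. Blood cell markers had 0.0314 (adjusted p = 0.206 with an estimated correlation; 0.161 without GADD45a+ING1b replicate 2; 0.18 without GADD45a+ING1bΔPHD replicate 1). With the replicate block 127 genes passed (98 up, 29 down). The count was 19 without either GADD45a+ING1b array and 29 without GADD45a+ING1bΔPHD replicate 1. These comparisons of the domain, with and without GADD45a in the label, share no array. Across genes their changes had r = 0.474, with 22 genes up and 5 down in both, where independent calls would share 0.212 and 0.00329.

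**Figure D3:**
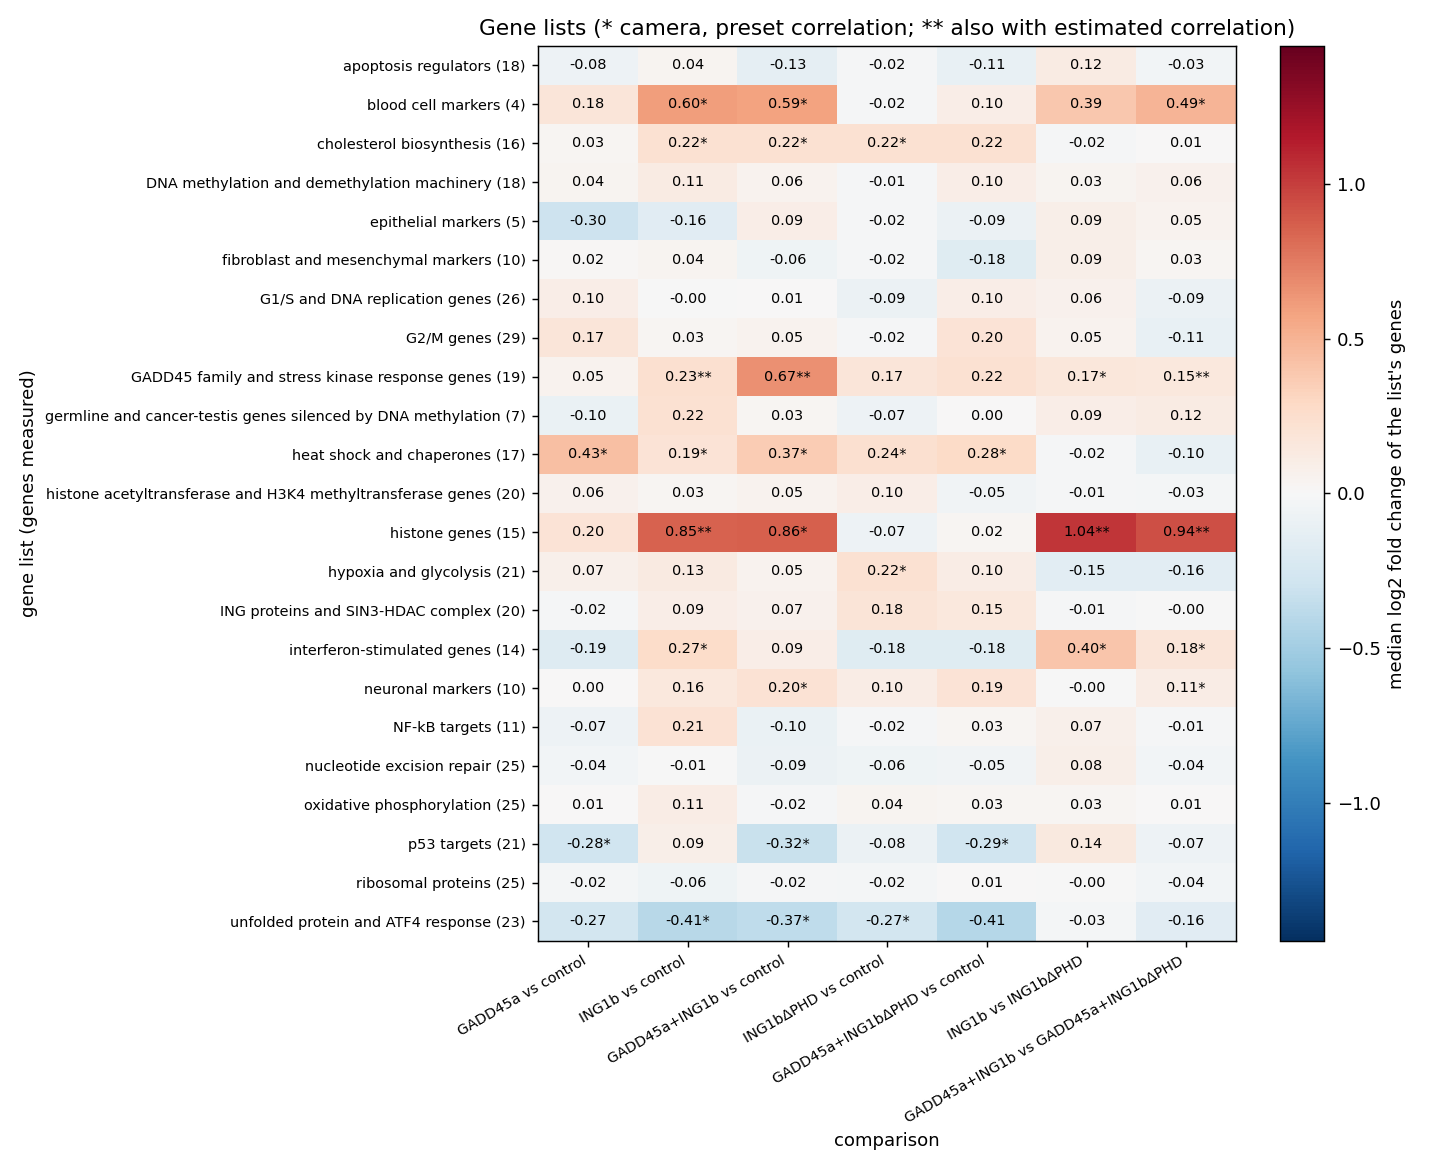
Median log2 change of each gene list (rows, with the number of genes measured) in 7 comparisons (columns), with red higher and blue lower. One star marks camera adjusted p under 0.05 with the preset correlation and a pair of stars also with an estimated one. Histone genes reach 1.04 in ING1b against ING1bΔPHD.

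Whether the effect of adding GADD45a differed between full-length ING1b and ING1bΔPHD was tested as a difference of differences. An unadjusted p under 0.05 was reached by 390 genes, fewer than the share of 0.05 of 10645 genes reached without any effect. By limma 1 gene passed, MYBPHL (downward, adjusted p = 0.0279). It was detected on both ING1b arrays (mean 7.04) and on 0 arrays of the other 3 groups (means 4.72, 4.68 and 4.76), so the test rests on its level in ING1b against background and gives no size. The block gave 3 genes (2 up, 1 down), MYBPHL with IQCN and TCIM, both upward and not detected in 3 of the 4 groups, which did not pass without it (adjusted p = 0.0513 and 0.0786). MYBPHL had an adjusted p of 0.0771 to 0.245 without any array outside the ING1b group. Without either ING1b array it was no longer tested, and 0 genes passed without any single array except GADD45a+ING1bΔPHD replicate 2, where 1 other gene passed.

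Among the 23 gene lists, 12 had no comparison with a camera adjusted p under 0.05. Their smallest camera adjusted p was 0.057 for germline and cancer-testis genes silenced by DNA methylation (7 measured of 41), 0.065 for G2/M genes, 0.0917 for oxidative phosphorylation, 0.152 for ribosomal proteins, 0.192 for ING proteins and the SIN3-HDAC complex, 0.203 for G1/S and DNA replication genes, and 0.277 for the DNA methylation and demethylation machinery. It was 0.311 for nucleotide excision repair, 0.443 for NF-kB targets, 0.475 for histone acetyltransferase and H3K4 methyltransferase genes, 0.561 for apoptosis regulators and 0.588 for epithelial markers. Among the 7 measured germline genes SPANXC, which has near-identical paralogs, was at least 1.29-fold higher in ING1b than in control and at least 1.17-fold lower in GADD45a+ING1b than in ING1b. The blood, neuronal, fibroblast and epithelial lists hold markers of other cell types, and HEK293T cells express many neuronal genes themselves.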

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

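All tests of explanations in this part were chosen only after the result was seen, and the list, gene and unnamed-probe results come from comparisons set beforehand. In the interaction of GADD45a and ING1bΔPHD, 2 lists were called by camera, and 3 with the replicate number as a block. Those called without the block were heat shock and chaperone genes (17 measured, median -0.26) and the unfolded protein and ATF4 response (23 measured, median 0.30). Each differed from the sum of the separate effects (camera adjusted p = 0.0414 for both). Neither held with an estimated correlation (adjusted p = 0.949 for both), the latter had 0.0632 under median scaling, their ranges over 15 alternatives were 4.99e-06 to 0.949 and 3.65e-08 to 0.978, and 0 members passed limma. Without Control replicate 2 they had 0.851 and 0.978, without GADD45a replicate 2 they had 0.148 and 0.0854, without ING1bΔPHD replicate 1 both had 0.141, and without GADD45a+ING1bΔPHD replicate 1 they had 0.319 and 0.0599. Without GADD45a replicate 1 both had 0.05, and the unfolded protein list had 0.15 without GADD45a+ING1bΔPHD replicate 2. MYBPHL differed in the effect of adding GADD45a between full-length ING1b and ING1bΔPHD (limma adjusted p = 0.0279, 0.00375 to 0.701 over 24 alternatives). Its fitted difference of -2.40 is not a size, since the probe was detected in ING1b and on 0 arrays of the other 3 groups. Interferon-stimulated genes differed in the same test (median -0.27, camera adjusted p = 0.0413; adjusted p = 0.545 with an estimated correlation; 0.0559 with the replicate block; 0.00152 to 0.545 over 15 alternatives). They had 0.0644 and 0.0643 without a GADD45a array, 0.111 and 0.0717 without an ING1b array, 0.353 without GADD45a+ING1b replicate 1, 0.148 without ING1bΔPHD replicate 1 and 0.295 without GADD45a+ING1bΔPHD replicate 2. Among the 3908 detected probes without a gene symbol, 20 passed in GADD45a+ING1b against control (14 up, 6 down), among them ILMN_1730818, a rise from detection on 1 of 2 control arrays, and ILMN_3234615, which was detected on both control arrays and on 0 of the others.

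The first pattern is the GADD45A probe ILMN_1694075, lost on the arrays with GADD45a in their label. Exchanged labels between single arrays with and without GADD45a are argued against by 0 of 12 arrays lying closer, over all genes but GADD45A, to the arrays with the other label, and background correction or normalization by the lowest signal without the label being 4.66 times the highest with it before any correction. A fall of all GADD45A message alike is argued against by the 2 probes' changes in GADD45a against control differing by at least 3.03 on the log2 scale, with the lost probe taken at the detection floor. A whole exchange between groups with and without GADD45a stays open, with a mean difference of -4.08 that includes undetected values, since probe positions were not used here and no value decides it. A loss of the endogenous message or part of it in cells that received the plasmid, the biological alternative, was not tested.

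The second pattern is a lower signal of detected probes on the arrays with GADD45a in their label. Over the 12916 probes detected on all arrays, the median above background was 350 to 409, against 429 to 490 without the label. The 75th percentile of all 47323 probes was 198 to 212 against 221 to 238 without (exact permutation test over 924 splits, two-sided p = 0.00216, n = 6 arrays each). As both sets did not overlap, this p is the smallest the splits can give. The pattern was chosen after it was seen, so the p is no independent evidence for it. Exact permutation within replicate numbers gave p = 0.005. A few genes taking more of the signal stays open: among arrays numbered replicate 1 the share of the 100 brightest probes was 13.6 to 14.2% with the label and 12.4 to 12.6% without, and among those numbered replicate 2 it was 12.4 to 13.3% and 11.7 to 12.0% (exact permutation within replicate numbers, p = 0.005, the smallest its 400 splits can give; 0.00866 over all 924). The summed signal of these probes, looked at after the share, was not higher with the label (log2 ratio -0.053), which does not decide it while the amount of labelled RNA is not known. Less labelled RNA on the arrays cannot be told apart from a change in the cells, since of 10 groups of probes ordered by brightness the brightest moved by -0.18 and the others by -0.24 to -0.28, and the amount loaded is not known. An effect of the transfected protein on total message was not tested.

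The third pattern is that 107 small nuclear and nucleolar RNA genes had their lowest median signals on the control arrays, with median changes of 0.31 in GADD45a, 0.30 in ING1b, 0.39 in GADD45a+ING1b, 0.54 in ING1bΔPHD and 0.50 in GADD45a+ING1bΔPHD. Of these genes 0, 1, 13, 0 and 1 rose in the same order. Control replicate 2 alone is argued against as the whole cause, since with Control replicate 1 as the only control the lowest of the 5 medians was 0.17. Normalization between arrays acts alike on genes of the same brightness, and is argued against as the whole cause. Under median scaling and the authors' values the median lay in all 5 groups above the highest of 1000 random lists of such genes. It was at least 0.35 above those lists' median. The 75th percentile scaling gave the same differences as median scaling, since a constant per array cancels in this comparison, and adds no further test. Without matching, the GADD45a median was 0.15 under median scaling, where the median of all genes moved by -0.23. These RNAs mostly lack a poly(A) tail, and a difference in RNA preparation of the control arrays or a response to any transfected protein was not tested.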

How the results depend on the processing

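All alternatives were planned before the data were examined, and none was added. For 258 calls of named genes (a gene in a comparison), 5432 of 6779 alternatives kept the call, 1347 lost it and 0 reversed. Alternatives in which a gene was not tested are not counted. Named genes were chosen mainly for large changes in these data, so this share does not describe all calls. For 267 pairs of a gene and a comparison that did not pass, 72 of 6955 alternatives gave a call. For 44 calls of 11 lists, 526 of 660 alternatives kept the call, 131 lost it and 3 reversed, all without Control replicate 2: ING1bΔPHD against control for heat shock (adjusted p 0.965, 2.84e-05 to 0.965 over single arrays left out) and the unfolded protein response (0.994, 8.18e-08 to 0.994), and the latter in the interaction with ING1bΔPHD (0.978, 3.65e-08 to 0.978). With the estimated correlation 8 of the 44 list calls were kept and 36 lost. Most of the 15 alternatives per list call left out 1 of the 12 arrays, so the pooled share mainly describes those. In what follows the comparisons against control are G (GADD45a), I (ING1b), GI (both), D (ING1bΔPHD) and GD (GADD45a with it), and other pairs are written out. Counts that moved by over 1.5 times were as follows, and the cause was not tested except for fewer arrays, fewer genes or a stricter threshold.

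No background correction gave 125 genes for G, 450 for GI, 122 for GD, 100 for GI against GD and 0 for the PHD dependence. An offset of 50 gave 0 for the PHD dependence. Median scaling gave 434 for G, 1517 for GI, 392 for GD and 58 for GI against I. The 75th percentile gave 35 for GD and 2 for the PHD dependence. The authors' deposited values gave 28 for GD, 2 for the interaction with ING1b, 1 for that with ING1bΔPHD and 2 for the PHD dependence. Without the detection filter GD had 19. Detection on all arrays gave 24 for I, 111 for GD, 30 for GI against G, 18 for GI against I, 21 for I against D, 30 for GI against GD and 0 for the PHD dependence. The mean over probes gave 32 for GD and 2 for the PHD dependence. Trend and robust gave 116 for G, 110 for GD, 97 for GI against GD and 0 for the PHD dependence. Array weights gave 40 for G, 156 for GI, 13 for GD and 2 for the PHD dependence. The replicate block gave 391 for G, 85 for I, 986 for GI, 3 for D, 645 for GD, 119 for GI against G, 64 for GI against I, 2 for the interaction with ING1b, 120 for I against D, 127 for GI against GD and 3 for the PHD dependence. Every gene that passed without the block also passed with it. Only the groups compared gave 1 for G, 25 for I, 49 for GI, 0 for GD, 23 for GI against G, 3 for GI against I, 23 for I against D, 20 for GI against GD and 0 for the PHD dependence. An adjusted p under 0.01 left 16 for G, 22 for I, 65 for GI, 6 for GD, 31 for GI against G, 15 for GI against I, 22 for I against D, 27 for GI against GD and 0 for the PHD dependence.

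Leaving out each array gave 5 to 144 for G, 8 to 69 for I, 51 to 423 for GI, 0 to 24 for D, 0 to 226 for GD, 21 to 59 for GI against G, 8 to 38 for GI against I, 0 to 0 for the interaction with ING1b, 0 to 1 for that with ING1bΔPHD, 6 to 53 for I against D, 19 to 54 for GI against GD and 0 to 1 for the PHD dependence. Counts against control were highest without Control replicate 1 (144, 69, 423, 24 and 226), and Control replicate 2 had the highest score on the first principal component (35.0, 22.7% of the variance). In every group replicate 2 scored above replicate 1 on the first component and below it on the second. Both components thus followed the replicate number, whose meaning across groups the labels do not give. A chip block was not run because the files name no chip. Signal over background limits these data, with 30.8 to 34.4% of probes detected per array.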

Other observations

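In this part the test of a response shared with HDAC inhibition was written before its result was seen, from a list recalled after the ING1b genes were known. SNORD3A, which encodes the U3 RNA of ribosome assembly, rose in GADD45a+ING1b against GADD45a (2.76, SE 0.4, limma adjusted p = 0.0126), and SNORA3B rose in GADD45a+ING1bΔPHD against control (1.14, SE 0.207, adjusted p = 0.0494). SERTAD1, a transcriptional co-regulator, rose in ING1b against control (2.05, SE 0.253, adjusted p = 0.00606) and VASN, a secreted-pathway antagonist of TGF-beta, was at least 4.01-fold higher. The kinase TYK2 was higher with the PHD domain both on arrays without GADD45a in their label (2.02, SE 0.277) and on those with it (2.15, SE 0.277).

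DHRS2, TUBB3 and histone genes rose with ING1b, and a candidate explanation is a response shared with HDAC inhibition. A list of 16 genes recalled as responding to such inhibitors, 13 of them measured, had a signed median of 0.17 in ING1b against control, at percentile 99.2 of 10000 random lists. In ING1b against ING1bΔPHD it was 0.052 at percentile 78.9, in GADD45a+ING1b against control 0.11 at 88.7, and in GADD45a+ING1b against GADD45a+ING1bΔPHD, where DHRS2 and TUBB3 also rose, -0.037 at 26.6 with 5 of 13 in the listed direction. In groups without full-length ING1b, against control, it was 0.099 at 88.98 (GADD45a+ING1bΔPHD), 0.025 at 64.05 (ING1bΔPHD) and -0.0016 at 52.02 (GADD45a). The deciding test, the limma rotation test fry with signs, did not pass 0.05 before adjustment (0.0775) or after it over 7 comparisons (adjusted p = 0.383), and 0 of the 13 genes passed limma in either direction. The data leave this open.

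Genes with several detected probes give a check on single probes. Of the 286 genes called in GADD45a+ING1b against control 63 had another detected probe, of which 10 were also called in the same direction. Against control it was 4 of 17 in GADD45a, 3 of 8 in ING1b and 0 of 17 in GADD45a+ING1bΔPHD. It was 1 of 9 in GADD45a+ING1b against GADD45a, 3 of 11 in ING1b against ING1bΔPHD and 4 of 11 in GADD45a+ING1b against GADD45a+ING1bΔPHD. In GADD45a+ING1b against ING1b it was 0 of 6, where the median ratio of the other probes' change to the called one was 0.00987, so those calls rest on single probes. In the other comparisons with such genes that ratio was 0.441 to 0.691.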
